A study of Mus musculus with 12 samples.

How the data were processed

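Expression was measured on Illumina mouse bead arrays in lin-cKit+Sca-1+ cells (LKS+ cells, the fraction of mouse bone marrow that holds stem cells and early progenitors) on the C57Bl6 background. Per the labels' protocols the cells were infected with the MIGR1 retroviral vector, either empty or carrying cSki, and GFP-positive cells were isolated 48 hours after infection. The labels put 6 arrays in each of the 2 groups and number them from 1 to 6. They describe alternative infection media without saying which sample received which. Nothing says whether the 6 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

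The deposited non-normalized table gives an intensity and a detection p-value for 45281 probes on each array, with no background subtraction. The intensities in the authors' table without background correction were identical to it, and the authors' background-corrected table differed from it by 1 constant per array, the mean intensity of that array's 936 negative control probes. The 2 deposited control tables, with 974 control probes, held identical intensities. Recomputed for all 45281 probes on each array, the deposited detection p-value matched, to within 0.00103, the share of all control probes, bright ones included, at or above the probe. A probe can therefore lie above every negative control without reaching a detection p of 0.01. The deposited series matrix holds values on a log2 scale, inferred from their match to background-subtracted intensities floored at 1. Their column medians lay between 4.3953 and 4.395775, and 29.5% to 33.4% of the values per array were 0. The software, its version and the array's annotation build were not given in the sources used here.

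Probes were named from the platform table (34885 probes), updated through gene identifiers to current RefSeq symbols, and otherwise from the symbols (2209 probes) or synonyms (1334 probes) in the authors' tables. The platform table gave several symbols for 18 probes, which were left unnamed, as were 6835 others. Where both sources named a probe, 99.6% of 25548 probes had matching names. No genome coordinates are given, because the build behind the array design was not given in the sources used here.

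Intensities were background-corrected by normexp with the negative controls (offset 16), quantile normalized together with the control probes and put on the log2 scale in limma 3.58.1 (R 4.3.3). Probes with a detection p under 0.05 on at least 6 arrays were kept, 16121 in all. Each gene was represented by its probe with the highest mean over the 12 arrays, and unnamed probes stayed as features of their own, which left 10841 features, 9560 of them with a symbol. Groups were compared with lmFit and eBayes without covariates, and p-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. Differences are on the log2 scale as arrays labelled cSki minus arrays labelled MIGR1, with the standard error (SE) of the fit. A gene detected on none of a group's arrays has only a bound there. Its change is given as at least N-fold, the mean of the other group against the mean, per array, of the higher of the lowest detected signal and the probe's own signal. Where only some arrays of a group detected a gene, their number is given. For a fold given as at least N-fold, each array of that group below its lowest detected signal, the floor, is raised to it. The other arrays keep the probe's own signal. These bounds hold only for the background-corrected values. Without that correction many of the differences were smaller than the bound.

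The 28 gene lists were tested with camera at a preset correlation of 0.01, with p-values adjusted over the lists by Benjamini-Hochberg. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance in 1 direction, were alternatives. Each list's median was also set against 10000 random lists matched on size and mean expression. The lists, their tests and the rule for naming genes were fixed before the data were examined. Other tests and alternatives that were chosen afterwards are named as such below. That rule takes Ski and Skil, the 12 largest rises and the 12 largest falls past the threshold, up to 4 members of each list with the smallest p, and Hgf, Met and Smad7 in any case. Some genes that the rule names are not reported here. It skipped unnamed gene models, 1 among the rises and 3 among the falls, and gave 127 names. Examples below come from it unless stated otherwise. Of 54 further probes for 40 of the named genes, 29 passed the threshold in the direction of the first probe and 23 did not pass. None passed opposite to a called first probe, and 2 passed opposite to a first probe that was not called. Among all genes, 228 of the 1025 with several called probes had called probes in opposite directions.

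The procedure was tested on simulated arrays in the same design with 17083 probes kept. It called 97.5% of the probes lowered by 2 on the log2 scale, 87.5% of those lowered by 1, 65.0% of those lowered by 0.5, 70.0% of those raised by 0.5 and 100% of those raised by 1. Among unchanged probes it called 0.0711%. Control probes of the real arrays were also taken through the same normalization and fit, and 19.6% of the negative controls passed the threshold. The simulated background varied around 1 mean per array, without differences of single probes between the groups. The 0.0711% therefore does not carry over to the real arrays. Simulated changes were placed only on probes brighter than a set level above background. They covered 40 probes per size, and 16883 of the 17083 probes were unchanged, whereas 47.9% of the real features were called. The percentages of changed probes called may therefore not carry over either. Alternatives covered the background correction, the scaling, the authors' processed values, the detection filter, the choice of probe, the replicate number as a block, array weights, a trended robust prior and each array left out in turn. Tables were read with pandas 2.3.3 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision.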

Results

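Transcript levels were compared between LKS+ cells that carried the empty MIGR1 retroviral vector and LKS+ cells infected with the same vector carrying cSki, a co-repressor known for restraining Smad proteins, the transcription factors of TGF-beta signalling. Each group had 6 arrays, and cells were sorted for the vector's GFP marker 48 hours after infection. Between 33.6% and 36.5% of the probes were detected on the arrays labelled MIGR1 and between 34.6% and 38.1% on those labelled cSki. Normalized values of 2 arrays of 1 group correlated across genes with r between 0.988 and 0.996, and those of arrays from different groups with r between 0.973 and 0.981.

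The probe for Ski, the gene placed in the vector, was lower on the arrays labelled cSki. Its normalized log2 intensity was 7.07 ± 0.11 (SD, n = 6) there and 8.69 ± 0.16 (SD, n = 6) on the arrays labelled MIGR1, and it fell by 1.62 on the log2 scale (SE 0.077, limma with Benjamini-Hochberg adjusted p = 4.6e-09), with all 6 arrays of a group on the same side. Without background correction it fell by 0.89. The other Ski probe was detected on none of the 12 arrays and differed by -0.04 (SE 0.12). Whether either probe lies in the part of the transcript carried by the vector, and from which species the cDNA came, is not given in the sources used here, so neither probe checks the labels. For that reason the groups are called arrays labelled cSki and arrays labelled MIGR1 throughout, and every direction below rests on those labels. Skil, the close relative of Ski, was detected on all 6 arrays labelled MIGR1 and on none labelled cSki, at least 3.56-fold lower (limma adjusted p = 1.07e-09). Without background correction the log2 difference of Skil was -1.08, smaller than this bound.

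The control probes also separated the groups. Mean biotin control intensity was 41425 ± 2368 (SD, n = 6) on the arrays labelled MIGR1 and 27408 ± 2789 on those labelled cSki. Mean negative control intensity was 231.2 ± 3.3 and 190 ± 7.34. These and 4 further array measures reached an exact two-sided permutation p of 0.00216, the smallest that 6 against 6 arrays can give (0.00289 after Benjamini-Hochberg adjustment over 8 measures). Housekeeping probes were also dimmer on the arrays labelled cSki (exact permutation p = 0.00866), while the percentage of probes detected did not differ past the threshold (exact permutation p = 0.119). Neither the labels nor the column names identify a BeadChip or batch, so the set of arrays and the group cannot be told apart in any result below. Taken through the same fit, 183 of the 936 negative control probes, which have no target, passed the threshold (19.6%, 95% exact binomial interval 17.1% to 22.2%), 94 higher and 89 lower.

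**Figure D1:**
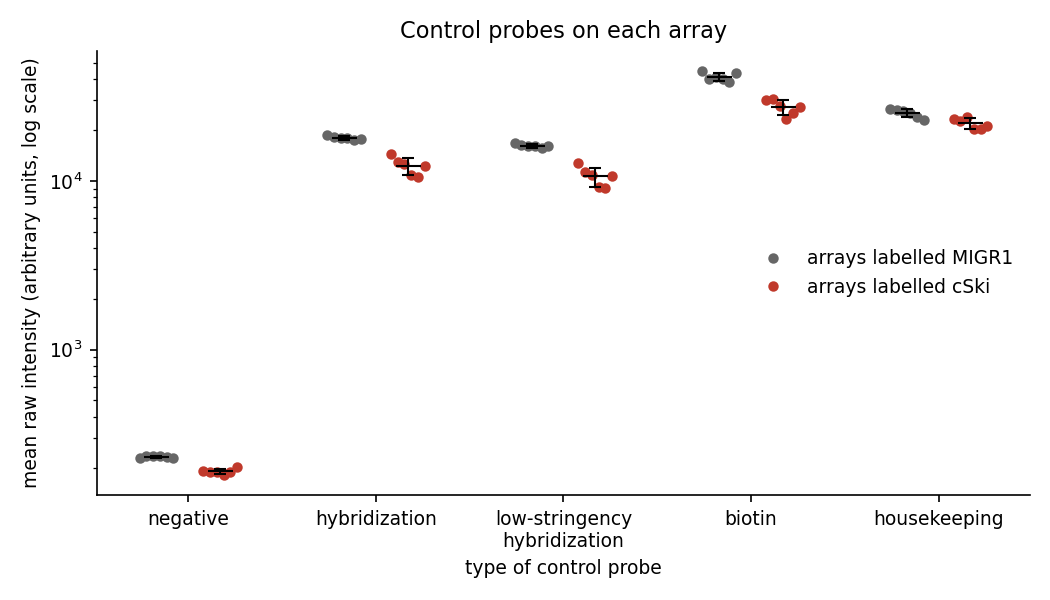
Mean raw intensity of 5 types of control probe on each array (points), with the mean and SD of each group (black), on a log axis in arbitrary units. The arrays labelled cSki lie below those labelled MIGR1 for the negative (180.3 to 202.5 against 227.2 to 234.6), hybridization and biotin controls.

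Against the empty vector, the large rises on the arrays labelled cSki included Chst2, a Golgi sulfotransferase (log2 difference 3.47, SE 0.11), and Unc45b, a myosin chaperone. Chst2 was detected on 1 array labelled MIGR1 and on all 6 labelled cSki, and was at least 7.57-fold higher on the latter. Unc45b was at least 4.23-fold higher, the small GTP-binding protein gene Gem at least 3.57-fold, the p38 kinase gene Mapk12 at least 3.35-fold, the ATP-gated channel gene P2rx3 at least 2.02-fold and the kinase gene Dmpk at least 1.62-fold, each detected on none of the arrays labelled MIGR1. Slc7a3, a cationic amino acid transporter, rose by 2.29 on the log2 scale, Selp, which encodes P-selectin, by 2.16, the muscle form of a cytochrome c oxidase subunit, Cox6a2, by 2.16, the tropomyosin gene Tpm4 by 2.04, Mrvi1, detected on 3 arrays labelled MIGR1, by 2.04 and Rgl1 by 1.94. For these 12 genes, limma adjusted p-values were at most 9.4e-08. Sizes and their order depended on the background treatment. The log2 differences of Chst2 (1.71), Unc45b (1.23), Gem (0.99), Mapk12 (0.96) and P2rx3 (0.77) without background correction were smaller than their bounds. That of Dmpk (0.74) was not. Without background correction Selp rose by 1.95, Tpm4 by 1.92 and Chst2 by 1.71, and the differences of 47 of the 115 named genes past the threshold were over 1.5 times smaller, with 0 changing sign. In the authors' processed values, which floor dim signals, the difference was 6.80 for Dmpk, 6.55 for P2rx3 and 4.27 for Chst2.

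Among the 12 largest falls, Camp, the cathelicidin of neutrophil granules, fell by 3.23 (SE 0.27) on the log2 scale, and Fcnb, which encodes ficolin B, fell by 2.36. They were detected on 3 and 4 of the arrays labelled cSki, and without background correction they fell by 1.90 and fell by 1.14. Ypel3 fell by 2.88, the transcription factor gene Bhlhe40 fell by 2.77, Abi3 fell by 2.33, the fatty acid desaturase gene Scd1 fell by 2.15 and the transporter gene Slc4a8, detected on 4 arrays labelled cSki, fell by 1.95. Mgarp was at least 3.11-fold lower, Palm3 at least 2.64-fold, the homeobox gene Irx3 at least 2.33-fold and the guidance receptor gene Robo1 at least 1.68-fold, each detected on all 6 arrays labelled MIGR1 and on none labelled cSki. Limma adjusted p-values for all these falls were at most 7.4e-05. Without background correction the log2 differences of Mgarp (-0.97), Palm3 (-0.72) and Irx3 (-0.78) were smaller than their bounds. That of Robo1 (-0.82) was not.

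**Figure D2:**
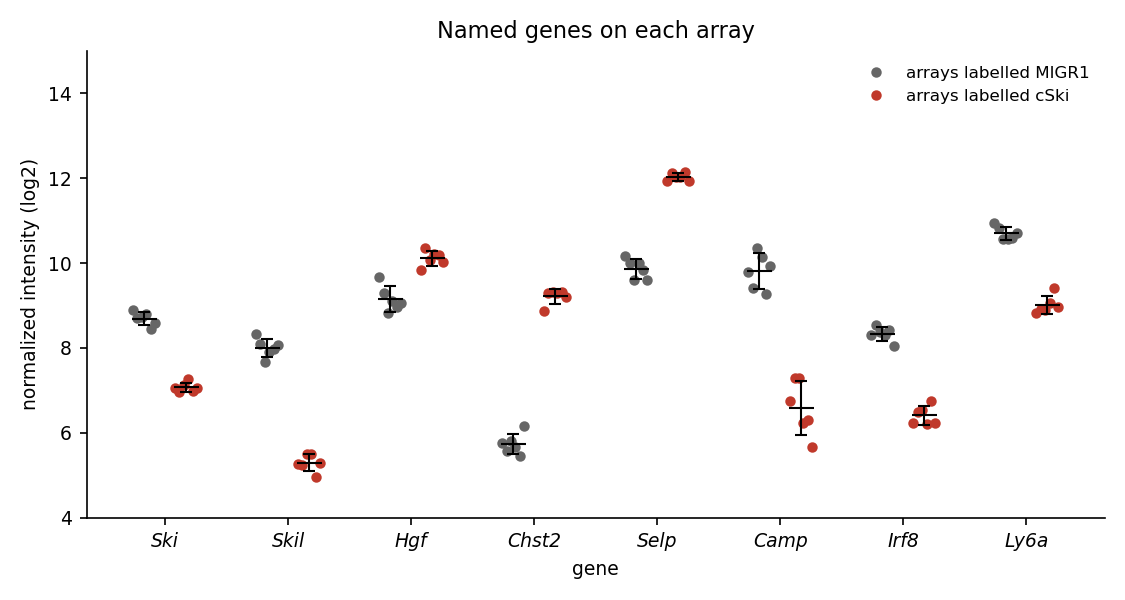
Normalized log2 intensity of 8 named genes on each array (points), with the mean and SD of each group of 6 arrays (black). Ski, Skil, Camp, Irf8 and Ly6a were lower and Hgf, Chst2 and Selp higher on the arrays labelled cSki, with no overlap between the groups.

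Over all 10841 features, 2848 were higher and 2347 lower on the arrays labelled cSki by limma with a Benjamini-Hochberg adjusted p under 0.05, which is 47.9% of the features. Changes beyond 1 on the log2 scale made up 137 of the rises and 254 of the falls, and 221 of those falls and 114 of those rises lay among the 3614 dimmest features. The groups did not overlap for 24.6% of the features, where chance gives 0.216%. Among the calls, 1209 rises and 723 falls lay outside the central 95% of the negative controls' own differences, -0.59 to 0.39. With median scaling over all probes in place of quantile normalization, which moved the median difference from 0.03 to 0.13, 71.1% of the calls were higher, against 54.8%. Median scaling over the kept probes alone, chosen after seeing the data, left the median difference at 0.03, with 53.8% of the calls higher.

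Among the TGF-beta induced targets, the transcripts that Ski and its partners are known to repress, 6 of the 11 measured members fell and 4 rose, with the same 6 and 4 when adjusted over the list alone. Bhlhe40 and Skil led the falls, Tgfbi fell by 1.30 (SE 0.13), and the cell cycle inhibitor gene Cdkn1c rose by 0.87 (SE 0.083). Camera did not place the list apart from the other genes (adjusted p = 0.105, and adjusted p = 0.353 with an estimated correlation), whereas fry, which tests only the members, gave an adjusted p of 2.6e-07 towards lower levels. With median scaling over all probes the camera adjusted p was 0.0216. The list's median lay at percentile 0.66 of the matched random lists. Smad7 was detected on no array. Of 12 measured TGF-beta and BMP receptors and Smads, 6 rose and 3 fell, as they did when adjusted over the list alone. Bmpr2 fell by 0.80, while Tgfbr3 rose by 0.80 and Smad3 by 0.50, its other probe differing by -0.15 (limma adjusted p = 0.331). Their camera adjusted p was 0.509, and fry gave an adjusted p of 0.0114 towards higher levels. Their median lay at percentile 98.39 of the matched random lists.

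Hgf, the ligand of the Met receptor, rose by 0.96 on the log2 scale (SE 0.13, limma adjusted p = 5.0e-05), and its further probes rose by 0.80 and 0.85. The probe that rose by 0.80 was detected on 4 arrays labelled MIGR1 and on all 6 labelled cSki. Its mean raw intensity was 342.2 on the arrays labelled MIGR1 and 329.6 on those labelled cSki, so its rise appeared only after processing. Met was detected on no array. Of the 25 measured members of HGF-Met signalling, 8 rose and 8 fell (9 and 9 when adjusted over the list alone), and camera gave an adjusted p of 0.947. Mapk3, which encodes ERK1, fell by 1.48 (without background correction it fell by 0.68) and the kinase gene Pik3ca fell by 0.86, while Pik3r1 rose by 0.49. The list's median lay above 0 (0.13) and its mean below (-0.07), with the camera test towards lower levels.

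Genes of hypoxia and glycolysis were lower as a group on the arrays labelled cSki. Of 14 measured members 12 fell and 0 rose, with the same 12 when adjusted over the list alone, and camera gave an adjusted p of 1.05e-05, which became an adjusted p = 0.353 with an estimated correlation. Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.46 (SE 0.10), the pyruvate dehydrogenase kinase gene Pdk1 fell by 0.75, and the glycolytic enzyme genes Aldoa and Eno1 fell by 0.74 and fell by 0.58, whereas Gapdh, outside the naming rule, differed by 0.01. Cholesterol synthesis genes followed, with 13 of 17 lower and 2 higher, also when adjusted over the list alone (camera adjusted p = 3.5e-04, and adjusted p = 0.353 with an estimated correlation). Msmo1 fell by 0.76, Lss fell by 0.69 and Sqle fell by 0.53. Against the random lists matched on mean expression, the medians of both lists lay at percentile 0. In the same arrays the biotin and negative controls were dimmer, as given above. Whether that contributed to the falls of these lists was not tested.

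Granulocyte and promyelocyte markers fell in 9 of 18 measured members and rose in 2, counts that were the same when adjusted over the list alone. The camera adjusted p was 0.00737, and the adjusted p = 0.353 with an estimated correlation. Beside Camp and Fcnb, Ngp fell by 1.92 (SE 0.10) and Ltf fell by 1.88 (SE 0.19). Of 3 members outside the naming rule, chosen after their values were seen, Lcn2 rose by 0.47 and Mmp8, detected on 2 arrays labelled MIGR1 and 5 labelled cSki, rose by 0.61, or by 0.29 with arrays below the floor set to it, and Mpo differed by 0.04 (limma adjusted p = 0.506). Mpo averaged 15.46 on the arrays labelled MIGR1 and 15.50 on those labelled cSki, and the brightest feature averaged 15.67. A change in a signal this bright may be understated. The p53 targets were higher as a group, 10 of 15 rising and 1 falling, likewise when adjusted over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.41 with an estimated correlation). Aen rose by 0.71, the death receptor gene Fas by 0.58, Sesn2 by 0.43 and Bax by 0.40.

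Markers of other blood cell types moved both ways, and camera placed none of these lists past the threshold. Against the matched random lists, the median lay at percentile 99.99 for megakaryocyte, 0.14 for mast cell and 1.2 for endothelial and stromal markers. For the others it lay between 5.53 and 94.39. Fry passed the megakaryocyte (adjusted p = 7.5e-05), mast cell (adjusted p = 0.0024) and monocyte (adjusted p = 0.0012) lists and none of the others in this paragraph. Stem cell markers rose in 8 of 17 measured members and fell in 4 (9 and 4 when adjusted over the list alone; camera adjusted p = 0.75). Mecom was at least 1.65-fold higher and Mllt3 rose by 0.83, while Ly6a, which encodes the sorting antigen Sca-1, fell by 1.69 (SE 0.10) and Cd34 fell by 0.77. Megakaryocyte and platelet markers rose in 8 of 12 and fell in 2, as they did when adjusted over the list alone (camera adjusted p = 0.105), with Selp, Plek (1.12 higher) and Pf4 (0.61 higher) among the rises and Cd9, which fell by 0.66. Monocyte, macrophage and dendritic cell markers rose in 4 of 11 and fell in 5 (5 and 5 when adjusted over the list alone; camera adjusted p = 0.678). The transcription factor gene Irf8 fell by 1.92 and Ctss fell by 1.05, detected on 5 and 2 arrays labelled cSki, Cx3cr1 was at least 1.36-fold lower and F13a1 rose by 0.88. Mast cell, basophil and eosinophil markers fell in 6 of 10 and rose in 2 (6 and 3 when adjusted over the list alone; camera adjusted p = 0.158), with Mitf, detected on 1 array labelled cSki, at least 1.87-fold lower and Cpa3 at 0.48. Erythroid markers rose in 2 of 7 and fell in 3 (2 and 4 when adjusted over the list alone; camera adjusted p = 0.75), with Klf1, detected on 1 array labelled cSki, at least 2.40-fold lower and Gfi1b at 0.89. Lymphoid markers rose in 2 of 8 and fell in 3 (3 and 5 when adjusted over the list alone; camera adjusted p = 0.881), and endothelial and stromal markers rose in 2 of 6 and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.855). The log2 differences of Mecom (0.39), Cx3cr1 (-0.36), Mitf (-0.43) and Klf1 (-0.60) without background correction were smaller than their bounds.

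Immediate-early genes rose in 7 of 12 measured members and fell in 0, also when adjusted over the list alone, with Zfp36 0.73 higher and Ier2, detected on 1 array labelled MIGR1, at least 1.44-fold higher. Their camera adjusted p was 0.0852, 0.0129 without MIGR1 replicate 1 and 0.0241 with no detection filter. The log2 difference of Ier2 without background correction (0.31) was smaller than its bound. Interferon response genes rose in 6 of 12 and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.122, and 0.0118 with no detection filter), with Oasl2 0.61 and Gbp2 0.54 higher. Hox and cofactor genes rose in 4 of 8 and fell in 0 (5 and 0 when adjusted over the list alone; camera adjusted p = 0.156), among them Meis1 by 0.32. NF-kB and inflammatory genes rose in 5 of 11 and fell in 3, as when adjusted over the list alone (camera adjusted p = 0.856). Tnf rose by 1.22 and Traf1, detected on 3 arrays labelled MIGR1, by 1.15, while Il6 fell by 1.07, and the list's median (-0.07) and mean (0.18) differed in sign.

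The remaining lists did not pass with camera either. DNA replication and mitosis genes rose in 4 of 28 and fell in 4, also when adjusted over the list alone (camera adjusted p = 0.75), and oxidative phosphorylation genes rose in 0 of 16 and fell in 3 (0 and 1 when adjusted over the list alone; camera adjusted p = 0.75). ER stress and amino acid response genes rose in 4 of 15 and fell in 2, also when adjusted over the list alone (camera adjusted p = 0.881), with Slc7a11 1.27 higher. STAT5 cytokine targets rose in 3 of 10 and fell in 2 (4 and 3 when adjusted over the list alone; camera adjusted p = 0.947), Ski co-repressor partners rose in 3 of 14 and fell in 2 (1 and 2 when adjusted over the list alone; camera adjusted p = 0.905), and retinoic acid targets rose in 2 of 3 and fell in 0, also when adjusted over the list alone (camera adjusted p = 0.235). Of the BMP targets 0 rose and 1 of 2 fell, of the Hedgehog targets 1 of 3 rose and 0 fell, and of the 3 Wnt targets and the 4 skeletal muscle genes measured 0 passed, all with unchanged counts when adjusted over the list alone (camera adjusted p = 0.881, 0.855, 0.881 and 0.947). Median and camera direction differed in sign for HGF-Met signalling, the BMP targets, the Ski co-repressor partners, the monocyte markers, the STAT5 targets, the ER stress genes and the NF-kB genes.

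**Figure D3:**
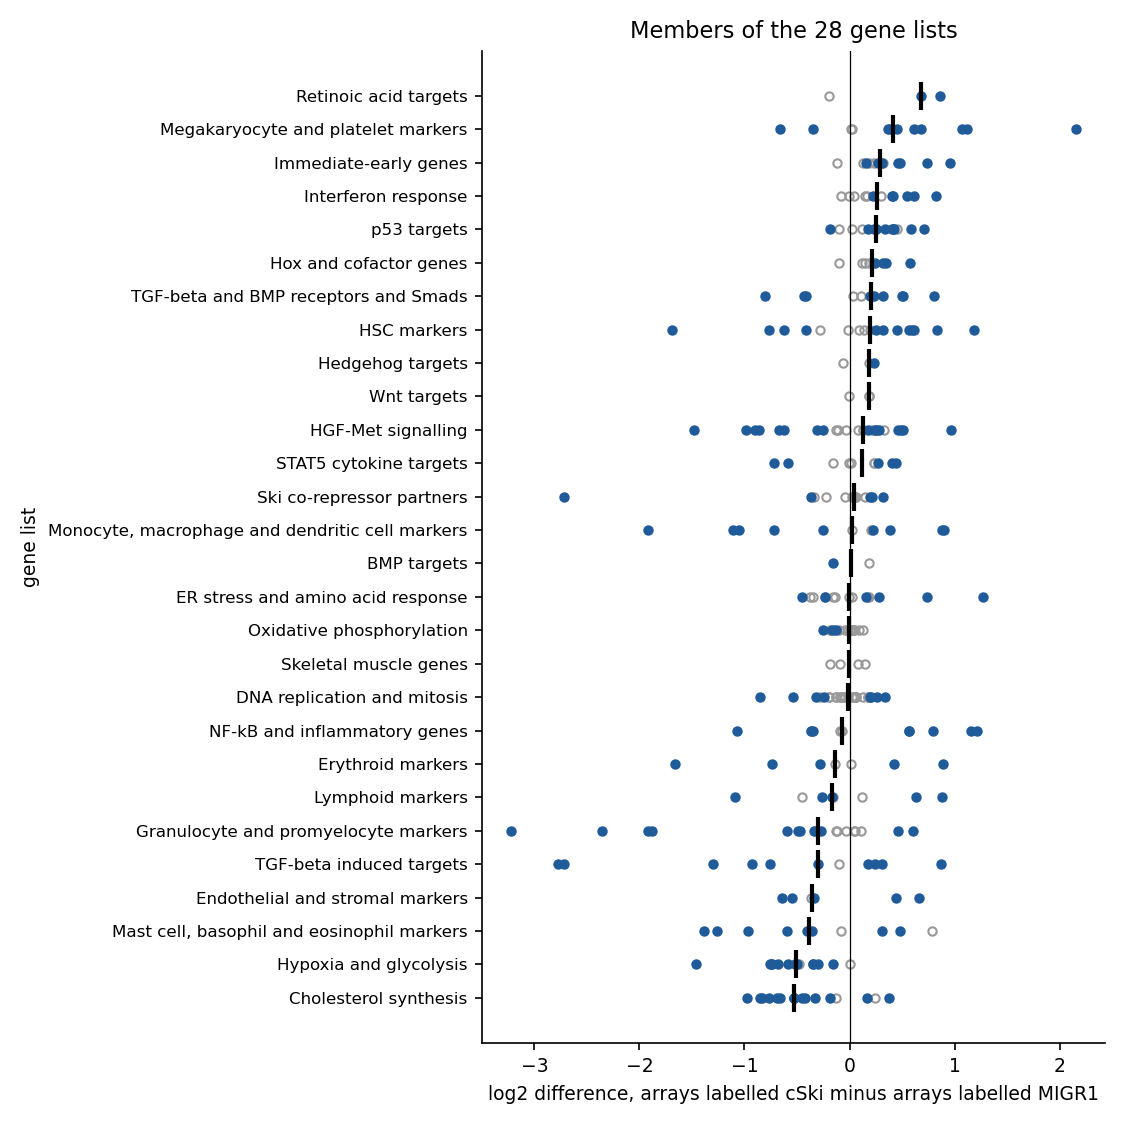
Log2 differences, arrays labelled cSki minus arrays labelled MIGR1, of the measured members of 28 gene lists (rows), with filled points for members past the adjusted threshold, open points for the others and a black bar at each list's median. Hypoxia and glycolysis (12 of 14 lower) and cholesterol synthesis (13 of 17 lower) have the lowest medians.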

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

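The comparisons of the Ski probe's raw signal with the positive and the negative controls were chosen only after the result was seen; the other tests in this part were written down before.

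In 17 of 266 groups of 6 values tested, over the named genes and 6 measures of array quality, 1 array lay apart from the others by Dixon's criterion at the 95% level. Chance alone flags 1 in 20 such groups, here about 13.3. Values are normalized log2 intensities. On MIGR1 replicate 6 this held for Abi3 at 8.78, with the nearest array at 9.06, Tnnc1 at 6.78, with the nearest array at 7.34 and Usp18 at 7.52, with the nearest array at 8.02. On MIGR1 replicate 2 this held for Ccl4 at 10.38, with the nearest array at 10.06 and Cox6c at 13.98, with the nearest array at 14.20. On cSki replicate 4 this held for Cd79b at 9.21, with the nearest array at 9.09. On cSki replicate 1 this held for Chst2 at 8.87, with the nearest array at 9.19 and P2rx3 at 6.59, with the nearest array at 7.32. On cSki replicate 2 this held for Dmpk at 7.29, above the other 5. On cSki replicate 6 this held for Gem at 8.29, with the nearest array at 8.12 and Tpm4 at 12.85, with the nearest array at 12.70. On MIGR1 replicate 1 this held for Gfi1b at 10.68, with the nearest array at 10.39, Mecom at 5.38, with the nearest array at 5.88, Phgdh at 10.35, with the nearest array at 10.86, Traf1 at 7.07, with the nearest array at 6.52 and Zfp36 at 10.67, with the nearest array at 10.22. On cSki replicate 5 this held for Oasl2 at 8.30, with the nearest array at 7.74.

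Between the groups 5195 features were called. The real split was the only 1 with as many among 100 splits of the 12 arrays, drawn from 462 possible, and the highest of the others gave 3. A chance division of these 12 arrays therefore does not account for the calls. A chance difference between single cultures cannot be excluded in this way, since the samples of a group may be technical. A difference in background and staining between the sets of arrays remains open as a part of the calls. Of the negative control probes 19.6% passed the threshold. This was less than the 47.9% of the features but well above what probes without a target should give. Among the hybridization controls, 4 of 6 Cy3 and 7 of 8 low-stringency probes passed, with median log2 differences of -0.21 and -0.29. The threshold was also passed by 1 of 2 biotin, 3 of 8 labelling and 4 of 14 housekeeping probes. The 19.6% is therefore not an estimate of the technical share of the calls. A BeadChip, or a batch of cells, RNA or labelling, that coincided with the group also stays open. No BeadChip is identified, and 0 batches named in the labels or column names hold arrays of both groups. The effect of cSki itself cannot be told apart from such a coincidence.

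The Ski probe was lower on the arrays labelled as carrying that gene in the vector. Weaker staining as the whole cause is argued against by the raw signal above background, which fell by 2.19 on the log2 scale (SE 0.12) while the largest fall among 16 biotin and hybridization controls was -1.13. Background alone is argued against by the raw intensity, which fell by 402.9 units (SE 26.6) where the largest fall of any negative control was -257.7, but an unusually high background of this probe together with weaker staining remains a possible explanation, as 2 of the 936 negative controls had normalized differences as low (range -1.91 to 0.98). Exchanged group labels could not be tested, as the second Ski probe (log2 difference -0.0383) was detected on no array. A fall of the cell's own Ski transcript under a vector-borne copy that the probe does not see may also account for it, and was not tested.

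The granulocyte and promyelocyte list was lower on the arrays labelled cSki (camera adjusted p = 0.00737), but not past the threshold with an estimated correlation (adjusted p = 0.353). A brightness-dependent effect of the normalization is argued against, since 0 of 10000 random lists matched on mean expression had a median as low. Fewer maturing granulocytic cells among the sorted cells may contribute and stays open: 2 members rose past the threshold, Lcn2, detected on all 12 arrays, and Mmp8, detected on only 2 arrays labelled MIGR1 and 5 labelled cSki, where a uniform loss of such cells predicts none and 3 had been set as the number that would exclude it. The lin-cKit+Sca-1+ selection would remove such cells, so they would have had to arise in culture afterwards or escape it. Some members of the list were bright in both groups. S100a8 averaged 15.11 on the arrays labelled MIGR1 and 15.08 on those labelled cSki, and S100a9 averaged 13.90 and 13.31. Which cells carried these transcripts was not tested, nor was an effect of cSki on these genes within cells.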

How the results depend on the processing

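The stricter filter on negative controls alone, the median scaling over kept probes and the test against a minimum change were chosen after seeing the data; the other alternatives were planned. No named gene or list past the threshold passed it in the opposite direction under an alternative, and the Ski probe stayed lower past it wherever it was fitted. Fry's direction opposed camera's for 3 lists, 0 of them past the threshold. Of the differences of the 115 called named genes, 47 were over 1.5 times smaller without background correction, 29 with the background-subtracted table and 5 with median scaling over all probes, where 1 was larger, as were 12 with the authors' processed values. The authors' processed values gave 2836 features higher and 2318 lower, and 98.2% of the 5195 calls were kept with their sign. Of the 115 called named genes, 9 lost the threshold with median scaling over all probes and 59 against the minimum change, in which no list was tested. Leaving out each array in turn gave 2527 to 2922 features higher, 2135 to 2358 lower, 1 to 2 lists higher and 3 lists lower. The second higher list was the immediate-early genes without MIGR1 replicate 1.

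Median scaling over all probes brought the number of lower features down to 1382, whereas over kept probes it gave 2670 higher and 2289 lower. With no detection filter 4042 features were higher and 4159 lower, so that falls outnumbered rises, and 3 lists were higher. Requiring the deposited detection p under 0.01 on all 12 arrays kept 154 features, of which 22 were higher and 25 lower, with 0 lists higher and 0 lower, because few features remained. Tested against a log2 change of 0.5, 205 features were higher and 336 lower. Camera with an estimated correlation gave 0 lists higher and 0 lower, and fry 7 and 7; the cause was not tested. The replicate block gave 2652 features higher and 2249 lower. After the group means were removed, 1 of 6 same-numbered pairs correlated above 0.1. By the same measure 2 MIGR1 arrays and 1 cSki array correlated best with their own number. These values give no sign that the numbers pair the arrays but cannot exclude it. The BeadChip as a block was not run, as no chip is named. The planned fit with surrogate variables was run once and could not be repeated, so no result of it is given. Dim signals also limit the results: the 3614 dimmest features hold 221 of the 254 falls and 114 of the 137 rises beyond 1 on the log2 scale, where signals lie closest to the negative controls.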

Other observations

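The test of muscle genes was set up after the largest rises were seen, and the genes in the next paragraph were also chosen after their values were seen.

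Further genes outside the naming rule moved by similar amounts. The p38 kinase gene Mapk11 rose by 1.71 on the log2 scale, beside Mapk12. The chemokine receptor gene Cxcr2 fell by 1.38. The desaturase gene Scd2 fell by 1.52 and the fatty acid synthase gene Fasn fell by 0.96. The transcription factor gene Gata3 rose by 1.52 and the interleukin receptor gene Il2ra by 1.39. All 6 passed the threshold in limma with Benjamini-Hochberg adjustment, the largest adjusted p being 6.7e-05 for Fasn.

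Several of the 12 largest rises, Unc45b, Cox6a2, Mapk12 and Dmpk, are genes known from muscle, and Ski is known for promoting muscle differentiation. The hypothesis that a wider set of skeletal muscle genes rose predicts at least 5 of the listed genes higher when dim probes are kept. With no detection filter, 3 of the 14 list members on the array were higher past the threshold and 0 lower, short of that number but above the limit of 2 below which the hypothesis was to be dropped. The 3 were Ckm (0.53), Des (0.42) and Myl1 (0.28), all near background, and differences of this size were also seen among negative controls, so a wider muscle response may or may not be present.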
